A study of Oryza sativa with 12 samples.

How the data were processed

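RNA was extracted from roots and shoots of rice with TRI-Reagent and a Direct-zol kit, per the labels' protocols. Polyadenylated RNA was sequenced from 12 libraries in 4 groups (WT root, OX6 root, WT shoot and OX6 shoot, n = 3 each), and groups and replicate numbers were taken from the sample titles. The letter P in the titles is not explained by the labels and was not used.

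The deposited table holds raw read counts per gene, made by the authors with HISAT2 2.0.5 and featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Coordinates are those of the file. Reads of overlapping or antisense genes and of near-identical paralogs may therefore be split or shared between genes. The table holds 57501 gene models, of which 55801 have a LOC_Os identifier, 1515 are models without a locus identifier and 185 are unplaced predictions. A protein name of the closest homologue is given for 26067 models and a Pfam domain for 35344. A name that the text gives as a domain rests on Pfam alone. The file does not pair LOC_Os09g15240 with the name ZAS, and that identity is background knowledge. A reference gene table of another annotation matched 0 identifiers and was not used here.

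Total counts ranged from 32269044 to 62910092 per library, with 28851 to 32074 genes holding a count. Replicates were compared by a chi-square of their counts per gene, which was 5.14 to 26.7 within groups, so no pair differed by as little as sampling noise and each library was counted once.

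Genes were tested with edgeR 4.0.16 (R 4.3.3) in 2 fits of 6 libraries, root and shoot, by the quasi-likelihood test with robust estimation, TMM scaling and filterByExpr (minimum count 10, minimum total count 15). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes under 0.05 were called. The interaction and the WT tissue comparison used 1 fit of all 12 libraries with a mean per group. The biological coefficient of variation was 9.61% in roots, 16.2% in shoots and 13.2% in the 12-library fit. All 753 genes called in roots and 1476 of 1481 called in shoots had no overlap between the replicate values of the genotypes. Chance gives this for 10% of genes not selected by a test. A call with 3 libraries per group nearly requires it, so it is no separate support. CPM values were scaled within a tissue. Standard errors are the absolute log2 fold change over the root of the F statistic.

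Before the data were examined, 31 gene lists with members, the tests, the alternatives and the rule for named genes were fixed. Lists were matched to the names in the file by keyword, so they carry some members outside their theme. Identifiers of another annotation in the lists matched 0 models. Dropped on their description were 7 putrescine hydroxycinnamoyltransferase models from the phosphate list, 1 cytochrome P450 88A1 model from the strigolactone list and 1 pinoresinol reductase model from the clock list. The strigolactone list lacks the CCD8 genes, which stand in the carotenoid cleavage list. Lists for plastid- and mitochondrion-encoded transcripts matched 0 models. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log-CPM with a prior count of 2, adjusted over lists of at least 5 tested members. With an estimated correlation, none of the camera calls held. At the preset correlation, other groupings of the libraries called up to 6 lists in roots and 7 in shoots. Fry tests whether a set's genes move, on balance, 1 way. Members were also counted with p-values adjusted over the list alone.

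The text names ZAS and every tested carotenoid cleavage gene. It adds, per tissue, the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM in the higher group, no replicate overlap and an informative name. From each list with called members it draws examples among the 4 of smallest adjusted p, and from other lists the most abundant member. For the interaction it takes the 5 genes of smallest adjusted p under the same limits on name and CPM, and for both tissues the 5 same-direction and 5 opposite-direction genes of smallest larger adjusted p among those with an informative name. A gene with no name or only a domain of unknown function was not counted as having one. Organ genes were the 200 with the largest fold in each direction of the WT tissue comparison with at least 10 CPM in their organ. They were chosen on these WT libraries.

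The alternatives were RLE and upper-quartile scaling, no count filter, a filter of CPM above 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, all 12 libraries in 1 fit, stricter thresholds (adjusted p under 0.01, or an absolute log2 fold change of at least 1), other set tests, and each library left out. Computations were tested on simulated counts, recovery being of the genes changed there, not of all low-count genes. In roots (26328 genes) edgeR recovered 92% of 2-fold and 69% of 1.5-fold changes, with 12.5% of 184 calls false. In shoots (25880 genes) it recovered 84% and 38%, with 8.96% of 134 calls false. Both false shares exceed the nominal 5%. The interaction (28717 genes) gave 62% and 11% with 0 false of 73 calls, and the tissue comparison (28629 genes) 78% and 57% with 8.78% of 148 false. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.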

Results

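Messenger RNA was profiled by RNA sequencing of polyadenylated transcripts in roots and shoots of 21-day-old hydroponically grown rice. Each tissue was taken from wild-type Nipponbare plants (WT) and from OX6, a line that overexpresses Zaxinone Synthase (ZAS). ZAS is a carotenoid cleavage dioxygenase that forms the apocarotenoid zaxinone. The 4 groups, WT root, OX6 root, WT shoot and OX6 shoot, held 3 libraries each. Total gene counts per library were 36464029, 36948155 and 36987990 in WT root and 35211101, 37583749 and 37910143 in OX6 root. In WT shoot they were 34355048, 62910092 and 37524787, and in OX6 shoot 39349561, 32269044 and 36669096. The 10 most abundant genes took 3.89 to 4.41% of the counts in roots, 11.5 to 12.3% in WT shoots and 10.4 to 10.6% in OX6 shoots. Values below are CPM (counts scaled by the effective library size) as mean ± SD of n = 3 libraries, and adjusted p-values come from edgeR. The labels do not say whether the replicates were separate plants or cultures, so p-values measure only the spread between these libraries, which may be technical. Gene names are those of the closest homologue given in the file, and "called" means an adjusted p under 0.05.

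The overexpressed gene was examined in every library to check the labels. The locus taken as ZAS from background knowledge, LOC_Os09g15240, chromosome 9, 9251214 to 9255028, carries the name carotenoid 9,10(9',10')-cleavage dioxygenase 1 in the file and lies on the minus strand. It had 120, 124 and 109 counts in the WT root libraries and 12637, 13559 and 14246 in the OX6 root libraries. The WT shoot libraries held 5, 26 and 7 counts and the OX6 shoot libraries 64950, 51763 and 53572. Expression therefore rose 113-fold in roots, from 3.21 ± 0.221 to 364 ± 7.92 CPM (log2 fold change 6.82, SE 0.0845, adjusted p = 1.04e-17). In shoots it rose from 0.254 ± 0.145 to 1533 ± 84 CPM (log2 fold change 12.38, SE 0.214, adjusted p = 5.89e-17; 13.10 without WT shoot replicate 2, which held 26 of the 38 WT counts). All 12 libraries were on the side of their genotype label.

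**Figure D1:**
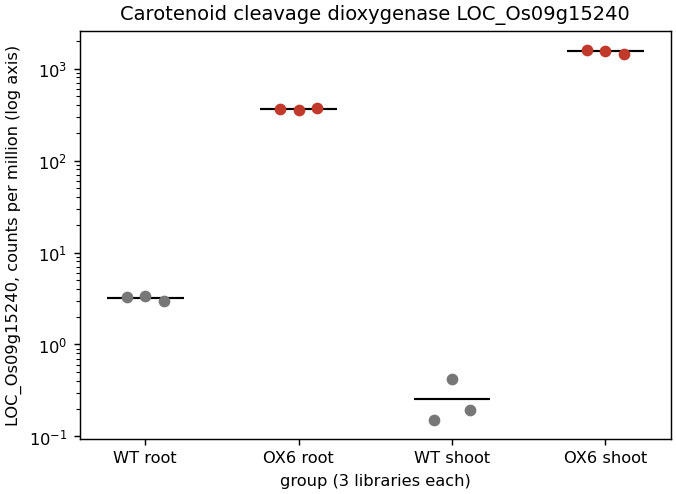
Expression of LOC_Os09g15240 in CPM (log axis) in the 4 groups, each point a library and each line the group mean; CPM was scaled within each tissue. The OX6 libraries lie near 364 CPM in roots and 1533 CPM in shoots, against 3.21 CPM in WT roots and 0.254 CPM in WT shoots.

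In roots, the comparison of OX6 with WT asked how the transcriptome of the overexpressing line differs. With 1 such line, here and in shoots, an effect of ZAS and another difference between the stocks cannot be told apart. The cytokinin response regulators ORR6, ORR9 and ORR10 rose 2.47- to 2.65-fold, and cytokinin hydroxylase, which forms trans-zeatin-type cytokinins, fell 2.31-fold. The abscisic acid receptors PYL5 and PYL2 and a 9-cis-epoxycarotenoid dioxygenase (NCED), an enzyme on the route to abscisic acid, fell 1.45- to 2.97-fold. A nitrate reductase gene (LOC_Os02g53130) and the nitrate transporters NPF4.4 and NPF6.3 fell 1.41- to 1.48-fold, while a phosphate transporter and a purple acid phosphatase rose 1.86- and 2.23-fold. Of 26574 genes tested, 753 were called, 317 higher and 436 lower in OX6, and 224 of them changed at least 2-fold (115 higher, 109 lower).

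Among the largest named changes in roots, the Copia protein gene (LOC_Os07g09760, chromosome 7, 5195696 to 5200918), named for a retrotransposon protein, rose from 0.118 ± 0.124 to 5 ± 0.418 CPM (adjusted p = 3.29e-06, log2 fold change 5.36, or 6.44 without WT root replicate 1). An early nodulin 93 gene (LOC_Os06g04930, chromosome 6, 2170890 to 2173400) rose from 0.154 ± 0.15 to 5.97 ± 2.01 CPM (adjusted p = 0.00163; log2 fold change 5.24, or 6.13 without WT root replicate 3). A TRAF-type zinc finger gene (LOC_Os05g23950, chromosome 5, 13783219 to 13785460) rose from 0.965 ± 0.29 to 6.64 ± 0.426 CPM (adjusted p = 4.85e-07). Anthocyanidin 3-O-glucosyltransferase (LOC_Os06g09240, chromosome 6, 4647954 to 4649523), which attaches glucose to flavonoids, rose 4.81-fold (adjusted p = 8.4e-08). The largest falls were in a copia-type gag gene (LOC_Os02g34760, chromosome 2, 20846402 to 20847993), from 7.99 ± 0.816 to 1.15 ± 0.279 CPM (adjusted p = 1.95e-07), and in SPX domain-containing protein 2 (LOC_Os02g10780, chromosome 2, 5706636 to 5709127), from 5.38 ± 0.951 to 1.15 ± 0.244 CPM (adjusted p = 8.33e-06). SPX proteins bind inositol pyrophosphates and dampen phosphate starvation signalling. Ethylene-responsive transcription factor ERF057 (LOC_Os03g09170, chromosome 3, 4780241 to 4781570) fell from 29.9 ± 2.92 to 6.8 ± 0.554 CPM (adjusted p = 3.52e-09). The ubiquitin ligase gene RDUF1 (LOC_Os07g43740, chromosome 7, 26173595 to 26174386) fell 4.32-fold and a wound-induced protein gene (LOC_Os04g54240, chromosome 4, 32301622 to 32302456) fell 3.8-fold (adjusted p = 3.69e-07 and 8.4e-08).

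Of the carotenoid cleavage dioxygenases in roots, 2 rose and 1 fell of 10 tested (2 and 1 adjusted over the list alone). Besides ZAS, carotenoid cleavage dioxygenase 8 homolog A (LOC_Os01g38580, chromosome 1, 21665618 to 21669309), of a family that forms the strigolactone precursor carlactone, rose from 2.73 ± 0.675 to 6.42 ± 1.87 CPM (adjusted p = 0.011). The NCED gene LOC_Os12g42280, chromosome 12, 26268230 to 26270794 fell from 8 ± 1.19 to 2.69 ± 0.584 CPM (adjusted p = 4.39e-05). The remaining members were not called. The CCD1 gene LOC_Os12g44310, chromosome 12, 27464735 to 27472036 had 32 ± 0.801 CPM in WT and 34.7 ± 2.91 CPM in OX6. CCD4 (LOC_Os02g47510, chromosome 2, 29026070 to 29028259) had 3.52 ± 1.04 CPM in WT and 2.36 ± 0.627 CPM in OX6. For CCD7 (LOC_Os04g46470, chromosome 4, 27567824 to 27570926) the values were 1.82 ± 0.446 CPM in WT and 2.04 ± 0.352 CPM in OX6. CCD8 homolog B (LOC_Os01g54270, chromosome 1, 31220321 to 31228566) had 1.32 ± 0.205 CPM in WT and 1.19 ± 0.45 CPM in OX6. Low expression was measured for NCED genes LOC_Os03g44380, chromosome 3, 24959107 to 24961777 (0.918 ± 0.0569 CPM in WT and 0.638 ± 0.285 CPM in OX6) and LOC_Os07g05940, chromosome 7, 2870686 to 2872832 (0.5 ± 0.151 CPM in WT and 0.301 ± 0.117 CPM in OX6). The same held for LOC_Os08g28240, chromosome 8, 17229167 to 17235488, which shares the file's name of ZAS, with 0.409 ± 0.117 CPM in WT and 0.166 ± 0.109 CPM in OX6. In the carotenoid precursor list in roots, 0 rose and 0 fell of 27 tested (0 and 0 adjusted over the list alone), and its most abundant member, deoxyxylulose phosphate synthase (LOC_Os06g05100, chromosome 6, 2250559 to 2256639), had 68.9 ± 2.06 CPM in WT and 71.6 ± 4.85 CPM in OX6. For strigolactone synthesis and signalling 0 rose and 0 fell of 8 tested (0 and 0 adjusted over the list alone), with the receptor D14 (LOC_Os03g10620, chromosome 3, 5422148 to 5426577) at 513 ± 85.1 CPM in WT and 511 ± 24.4 CPM in OX6.

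Abscisic acid turnover and receptor genes in roots shifted downwards as a list (camera adjusted p = 0.00108, median log2 fold change −0.245; adjusted p = 0.744 with an estimated correlation), and 0 rose and 3 fell of 15 tested (0 and 5 adjusted over the list alone). Receptor PYL5 (LOC_Os05g39580, chromosome 5, 23239202 to 23240677) fell from 54.1 ± 1.73 to 37.4 ± 2.97 CPM (adjusted p = 0.000426). PYL2 (LOC_Os06g36670, chromosome 6, 21556404 to 21557334) fell from 7.79 ± 1.23 to 4.9 ± 0.348 CPM (adjusted p = 0.0159), the NCED gene LOC_Os12g42280 being the other member called. Among cytokinin genes, 6 rose and 2 fell of 42 tested (6 and 2 adjusted over the list alone). The response regulators ORR6 (LOC_Os04g57720, chromosome 4, 34375978 to 34377357), ORR9 (LOC_Os11g04720, chromosome 11, 2013371 to 2015405) and ORR10 (LOC_Os12g04500, chromosome 12, 1915856 to 1917598), which are induced by cytokinin and feed back on its signalling, rose 2.47-fold, 2.63-fold and 2.65-fold. Their adjusted p-values were 2.02e-07, 9.33e-07 and 5.42e-07. ORR9 and ORR10 lie in the duplicated ends of chromosomes 11 and 12, so the split of reads between them is uncertain. Cytokinin hydroxylase (LOC_Os08g33300, chromosome 8, 20761534 to 20763853) fell from 15.9 ± 0.639 to 6.88 ± 0.312 CPM (adjusted p = 1.68e-06).

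Of the other hormone lists in roots, for auxin 2 rose and 1 fell of 171 tested (0 and 1 adjusted over the list alone), an example being the auxin efflux carrier PIN5b (LOC_Os09g32770, chromosome 9, 19549906 to 19552405), which fell 1.55-fold (adjusted p = 0.00163). Gibberellin genes gave counts in which 2 rose and 2 fell of 42 tested (5 and 4 adjusted over the list alone). A gibberellin 2-beta-dioxygenase (LOC_Os01g55240, chromosome 1, 31795105 to 31797643), which inactivates gibberellin, fell 1.39-fold (adjusted p = 0.032). For jasmonate 0 rose and 0 fell of 67 tested (0 and 0 adjusted over the list alone), and linoleate 9S-lipoxygenase 2 (LOC_Os03g52860, chromosome 3, 30315455 to 30318972) had 235 ± 3.14 CPM in WT and 204 ± 37.7 CPM in OX6. For ethylene 1 rose and 7 fell of 131 tested (2 and 11 adjusted over the list alone), the falls including ERF057 and RAP2-3 (LOC_Os05g29810, chromosome 5, 17246963 to 17248264, 1.76-fold, adjusted p = 0.00163).

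Mineral nutrition genes of roots went both ways. In the phosphate starvation list 6 rose and 1 fell of 72 tested (10 and 1 adjusted over the list alone). Purple acid phosphatase 22 (LOC_Os11g05400, chromosome 11, 2423603 to 2426866), of a family that releases phosphate from organic compounds, rose from 15.4 ± 2.62 to 34.2 ± 4.99 CPM (adjusted p = 0.00048). Phosphate transporter 1-2 (LOC_Os03g05640, chromosome 3, 2815438 to 2817367) rose from 60.8 ± 8.22 to 113 ± 13.2 CPM (adjusted p = 0.000799), and the fall was that of SPX domain-containing protein 2. For nitrate and ammonium 0 rose and 4 fell of 61 tested (0 and 6 adjusted over the list alone). Nitrate reductase (LOC_Os02g53130, chromosome 2, 32513739 to 32517155), which reduces nitrate to nitrite, fell from 226 ± 14.9 to 153 ± 7.45 CPM (adjusted p = 9.13e-05). A further nitrate reductase gene (LOC_Os08g36480, chromosome 8, 23033230 to 23038596), named after its values were seen, had 106.8 ± 13.5 CPM in WT and 65.6 ± 12.1 CPM in OX6 (adjusted p = 0.0564). Its adjusted p was 0.022 without OX6 root replicate 1, 0.00684 without OX6 root replicate 2 and 0.0345 in 1 fit of all 12 libraries. The highest over the alternatives was 0.174. The transporters NPF4.4 (LOC_Os11g12740, chromosome 11, 7193230 to 7198552) and NPF6.3 (LOC_Os10g40600, chromosome 10, 21757768 to 21762202) fell 1.48-fold and 1.41-fold (adjusted p = 0.0114 and 0.0124). In the iron and zinc list 1 rose and 3 fell of 60 tested (1 and 8 adjusted over the list alone). Vacuolar iron transporter 1.2 (LOC_Os09g23300, chromosome 9, 13831868 to 13833654) fell from 49.8 ± 3.84 to 24.1 ± 2.62 CPM (adjusted p = 2.11e-06). Nicotianamine synthase 3 (LOC_Os07g48980, chromosome 7, 29323094 to 29324723), which makes a metal chelator, rose 1.35-fold (adjusted p = 0.00772). Of the potassium, sulfate and other mineral transporters 0 rose and 0 fell of 78 tested (0 and 0 adjusted over the list alone), the silicon channel NIP2-1 (LOC_Os02g51110, chromosome 2, 31266245 to 31269960) having 3498 ± 346 CPM in WT and 3363 ± 389 CPM in OX6.

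Photosynthetic light reaction genes shifted downwards in roots (camera adjusted p = 0.00108, median log2 fold change −0.306, or −0.162 without OX6 root replicate 1 and −0.19 without WT root replicate 1; adjusted p = 0.744 with an estimated correlation), although 0 rose and 1 fell of 64 tested (0 and 1 adjusted over the list alone). The member called was chlorophyll a-b binding protein 1 (LOC_Os09g17740, chromosome 9, 10845678 to 10847156), which fell from 9.46 ± 1.97 to 4.41 ± 1.13 CPM (adjusted p = 0.00811). The 200 most shoot-enriched genes, a sign of shoot tissue, made up 0.00624% ± 0.0016 (SD, n = 3) of counts in WT roots and 0.00399% ± 0.00156 in OX6 roots. For the 165 of them outside the photosynthesis lists, the share in roots was 0.0205% ± 0.00262 of that in WT shoots for WT and 0.0225% ± 0.00495 for OX6, and the 6 of these tested in roots had a median log2 fold change of −0.596 (quartiles −0.795 and −0.47). Calvin cycle and photorespiration genes gave a count in which 0 rose and 0 fell of 58 tested (0 and 0 adjusted over the list alone), with glycine dehydrogenase (LOC_Os01g51410, chromosome 1, 29560350 to 29567065) at 252 ± 6.54 CPM in WT and 224 ± 17.6 CPM in OX6. Of the chlorophyll and tetrapyrrole genes 0 rose and 1 fell of 32 tested (0 and 1 adjusted over the list alone), siroheme synthase (LOC_Os01g44050, chromosome 1, 25234661 to 25238165), which makes the cofactor of nitrite reductase, falling from 159 ± 5.76 to 124 ± 1.07 CPM (adjusted p = 0.00212). In the sucrose and starch list 1 rose and 0 fell of 149 tested (0 and 0 adjusted over the list alone). In the glycolysis and tricarboxylic acid cycle list 0 rose and 2 fell of 164 tested (0 and 1 adjusted over the list alone).

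Cell wall and defence genes of roots also went both ways. In the cell wall expansion list 7 rose and 9 fell of 284 tested (20 and 11 adjusted over the list alone), and pectinesterase 41 (LOC_Os01g20980, chromosome 1, 11715165 to 11717784) fell 1.45-fold (adjusted p = 0.000509). Among class III peroxidases 10 rose and 3 fell of 132 tested (16 and 9 adjusted over the list alone). Peroxidase SPC4 (LOC_Os01g73170, chromosome 1, 42429502 to 42432618) rose from 142 ± 5.08 to 216 ± 21 CPM (adjusted p = 8.78e-05), and peroxidase 3 (LOC_Os07g01420, chromosome 7, 264525 to 265650) rose 1.39-fold (adjusted p = 0.00295). Pathogenesis-related genes gave a count in which 6 rose and 5 fell of 269 tested (10 and 9 adjusted over the list alone). Glucan endo-1,3-beta-glucosidase 13 (LOC_Os07g35350, chromosome 7, 21150011 to 21152329) rose 2.84-fold and the activator PTI5 (LOC_Os01g54890, chromosome 1, 31567891 to 31568741) fell 1.62-fold (adjusted p = 1.82e-06 and 0.00207). In the phenylpropanoid list 7 rose and 8 fell of 260 tested (9 and 9 adjusted over the list alone). There were falls in isoflavone reductase homolog IRL (LOC_Os01g01660, chromosome 1, 327128 to 328451, 1.6-fold) and laccase-22 (LOC_Os11g48060, chromosome 11, 28973120 to 28976343, 1.58-fold) at adjusted p of 3.28e-06 and 0.00013. For diterpenoid phytoalexins 0 rose and 1 fell of 40 tested (0 and 2 adjusted over the list alone), the member called being ent-cassadiene C2-hydroxylase (LOC_Os01g72740, chromosome 1, 42206304 to 42208513, 1.39-fold lower, adjusted p = 0.000675). Of the aquaporins 2 rose and 3 fell of 45 tested (5 and 3 adjusted over the list alone), and PIP2-6 (LOC_Os07g26640, chromosome 7, 15369135 to 15370167), a water channel, fell 1.69-fold (adjusted p = 5.63e-05).

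Heat shock genes shifted downwards in roots (camera adjusted p = 0.0337, median log2 fold change −0.0456, or −0.0696 without OX6 root replicate 2; adjusted p = 0.744 with an estimated correlation), and 0 rose and 9 fell of 146 tested (0 and 10 adjusted over the list alone). Heat shock cognate 70 kDa protein (LOC_Os03g16860, chromosome 3, 9370159 to 9373083), a chaperone, fell from 372 ± 26.7 to 231 ± 8.83 CPM (adjusted p = 9.9e-06). Heat stress factor B-2b (LOC_Os08g43334, chromosome 8, 27380765 to 27390339) fell 3.21-fold (adjusted p = 3.34e-05). Ribosomal protein genes shifted slightly downwards (camera adjusted p = 0.00108, median −0.0611, or −0.0324 without OX6 root replicate 2; adjusted p = 0.744 with an estimated correlation), but 0 rose and 0 fell of 333 tested (0 and 0 adjusted over the list alone). Acidic protein P1 (LOC_Os08g02340, chromosome 8, 904112 to 905710) had 763 ± 36.8 CPM in WT and 735 ± 54.9 CPM in OX6. For late embryogenesis abundant proteins 1 rose and 0 fell of 62 tested (1 and 0 adjusted over the list alone), the rise being in LOC_Os12g03370, chromosome 12, 1309401 to 1310704 (1.57-fold, adjusted p = 0.00629). In the histone and cell cycle list 2 rose and 0 fell of 121 tested (2 and 0 adjusted over the list alone). In the symbiosis list 1 rose and 0 fell of 52 tested (1 and 0 adjusted over the list alone). Of the transposon-related genes 13 rose and 7 fell of 566 tested (14 and 8 adjusted over the list alone). For the circadian clock 0 rose and 0 fell of 9 tested (0 and 0 adjusted over the list alone), GIGANTEA (LOC_Os01g08700, chromosome 1, 4329152 to 4338486) having 1251 ± 44.6 CPM in WT and 1231 ± 45.5 CPM in OX6. The 27 root lists that camera did not call had adjusted p of 0.0593 to 0.949. Median and mean differed in sign for the carotenoid cleavage, mineral transporter, auxin, aquaporin and transposon lists.

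The root count was 459 without WT root replicate 2, 407 without WT root replicate 3 and 293 (119 higher, 174 lower) in 1 fit of all 12 libraries, which also changed the scaling and the genes tested and ended 10 of the named calls at adjusted p of 0.0672 to 0.377 (PYL2, phosphate transporter 1-2, NPF4.4, NPF6.3, nicotianamine synthase 3, PIN5b, the gibberellin 2-beta-dioxygenase, pectinesterase 41, peroxidase 3 and LOC_Os12g03370). Without 1 library PYL2, NPF4.4, NPF6.3 and the gibberellin 2-beta-dioxygenase also lost their calls (adjusted p of 0.0662 to 0.131), and the heat shock call ended without WT root replicate 2 (adjusted p = 0.0598), WT root replicate 3 (0.0668), OX6 root replicate 1 (0.199) or OX6 root replicate 3 (0.0956), and the ribosomal call without OX6 root replicate 2 (0.106).

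In shoots, the comparison of OX6 with WT asked the matching question for the aerial tissue. The nitrate reductase gene LOC_Os02g53130 rose 5.9-fold, while the more abundant nitrate reductase gene LOC_Os08g36480 rose from 96.8 to 149 CPM, and the nitrate transporter NPF6.3, siroheme synthase and an ammonium transporter rose 1.85- to 3.19-fold, while high-affinity nitrate transporter 2.4 fell 2.25-fold. In the lists of the photosynthetic light reactions, the Calvin cycle and chlorophyll synthesis 12, 6 and 5 genes fell, with folds of 1.39 to 1.51 for the examples below. In the sucrose, starch and sugar transport list 11 genes rose and 7 fell, the rises including a trehalose-phosphate synthase (2.31-fold) and sugar transport protein 1 (2.24-fold). Of 26251 genes tested, 1481 were called, 834 higher and 647 lower in OX6 (783 and 799 under upper-quartile scaling), and 397 changed at least 2-fold (279 higher, 118 lower).

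The largest named rises in shoots, after ZAS, were in transposon-related genes. The Copia protein gene LOC_Os07g09760 rose from 0.0199 ± 0.0174 to 6.45 ± 0.82 CPM (adjusted p = 1.61e-09; 3 counts over the WT libraries). A reverse transcriptase zinc-binding gene (LOC_Os10g14180, chromosome 10, 7685221 to 7696843) rose from 8.53 ± 0.779 to 73.5 ± 9.4 CPM (adjusted p = 3.18e-11). A RICESLEEPER 2 gene (LOC_Os06g40240, chromosome 6, 23967708 to 23976387) rose from 3 ± 1.16 to 24.8 ± 1.62 CPM (adjusted p = 9.57e-07). Cysteine-rich receptor-like protein kinase 15 (LOC_Os11g10710, chromosome 11, 5873795 to 5880713) rose 7.05-fold (adjusted p = 1.25e-07). SPX domain-containing protein 2 fell from 6.06 ± 0.209 to 1.82 ± 0.506 CPM (adjusted p = 0.000178), and ACR3 (LOC_Os02g34990, chromosome 2, 20985923 to 20994251), with amino acid-binding ACT domains, fell 3.14-fold (adjusted p = 8.01e-06). Peroxidase 2 (LOC_Os07g48010, chromosome 7, 28669498 to 28671387), dirigent protein 4 (LOC_Os11g10850, chromosome 11, 5978417 to 5978986) and arginine decarboxylase 2 (LOC_Os04g01690, chromosome 4, 463738 to 467284), which starts polyamine synthesis, fell 3.21-fold, 2.62-fold and 2.62-fold (adjusted p = 0.0263, 0.02 and 0.00033).

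Of the carotenoid cleavage dioxygenases in shoots, 1 rose and 2 fell of 10 tested (1 and 3 adjusted over the list alone). CCD8 homolog A fell from 15.3 ± 4.32 to 9.07 ± 1.15 CPM (adjusted p = 0.0254) and CCD4 (LOC_Os02g47510) fell from 970.1 ± 121 to 727 ± 29.6 CPM (adjusted p = 0.0264). Members that were not called were CCD1 (LOC_Os12g44310) with 116 ± 3.5 CPM in WT and 115 ± 3.78 CPM in OX6 and CCD7 with 4.54 ± 0.77 CPM in WT and 3.47 ± 0.444 CPM in OX6. The others included CCD8 homolog B with 0.847 ± 0.139 CPM in WT and 0.489 ± 0.28 CPM in OX6. NCED genes LOC_Os12g42280 and LOC_Os03g44380 had 3.72 ± 1.1 CPM in WT and 4.14 ± 1.81 CPM in OX6, and 2.07 ± 1.09 CPM in WT and 1.08 ± 0.22 CPM in OX6. A further CCD4 gene (LOC_Os12g24800, chromosome 12, 14232903 to 14234903) had 7.15 ± 2.48 CPM in WT and 3.99 ± 0.805 CPM in OX6 (adjusted p = 0.0533), and LOC_Os08g28240 had 0.622 ± 0.17 CPM in WT and 1.09 ± 0.122 CPM in OX6. In the carotenoid precursor list 0 rose and 3 fell of 29 tested (0 and 3 adjusted over the list alone). Beta-carotene hydroxylase 2 (LOC_Os04g48880, chromosome 4, 29157213 to 29159281) and phytoene synthase (LOC_Os12g43130, chromosome 12, 26780487 to 26783598), the entry to the carotenoid pathway, fell 1.82-fold and 1.4-fold (adjusted p = 0.000239 and 0.0131). For strigolactones 1 rose and 3 fell of 10 tested (1 and 3 adjusted over the list alone). The isomerase D27 (LOC_Os08g02210, chromosome 8, 751274 to 753264), at the start of strigolactone synthesis, fell 1.3-fold (adjusted p = 0.0228) and the receptor D14 rose from 172 ± 26.8 to 261 ± 14.8 CPM (adjusted p = 0.00361). The signalling repressors DWARF 53 (LOC_Os11g01330, chromosome 11, 194176 to 199479) and DWARF 53-LIKE (LOC_Os12g01360, chromosome 12, 220456 to 225846), which lie in the duplicated ends of chromosomes 11 and 12 and may share reads, fell 1.72-fold and 1.58-fold (adjusted p = 0.007 and 0.0131).

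Nitrate and ammonium genes in shoots went both ways, and 5 rose and 4 fell of 62 tested (5 and 8 adjusted over the list alone). Nitrate reductase gene LOC_Os02g53130 rose from 8.11 ± 2.04 to 47.7 ± 2.53 CPM (adjusted p = 8.03e-09) and LOC_Os08g36480 from 96.8 ± 22.7 to 149 ± 3.43 CPM (adjusted p = 0.0113). Ammonium transporter 2 member 3 (LOC_Os01g61510, chromosome 1, 35585865 to 35588377) rose from 2.38 ± 0.446 to 7.66 ± 1.68 CPM (adjusted p = 0.000137) and NPF6.3 rose from 18.3 ± 3.69 to 34 ± 5.68 CPM (adjusted p = 0.00176). High-affinity nitrate transporter 2.4 (LOC_Os01g36720, chromosome 1, 20386195 to 20388517) fell from 8.06 ± 2.51 to 3.58 ± 0.234 CPM (adjusted p = 0.00324). In the phosphate starvation list 5 rose and 6 fell of 70 tested (7 and 7 adjusted over the list alone), with phosphate transporter 1-1 (LOC_Os03g05620, chromosome 3, 2807555 to 2809678) rising 1.8-fold and purple acid phosphatase 22 falling 1.73-fold (adjusted p = 0.0003 and 0.0013). For iron and zinc 1 rose and 1 fell of 52 tested (3 and 2 adjusted over the list alone), nicotianamine synthase 3 falling 1.67-fold (adjusted p = 0.00773). Among other mineral transporters 1 rose and 1 fell of 77 tested (1 and 1 adjusted over the list alone), and potassium transporter 7 (LOC_Os07g47350, chromosome 7, 28312108 to 28317670) rose 1.78-fold (adjusted p = 0.000121).

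Photosynthetic light reaction genes shifted downwards in shoots (camera adjusted p = 4.54e-06, median log2 fold change −0.185; adjusted p = 0.787 with an estimated correlation), and 0 rose and 12 fell of 94 tested (1 and 22 adjusted over the list alone). Chlorophyll a-b binding protein 1, an antenna protein, fell 1.39-fold (adjusted p = 0.00865). Leaf ferredoxin--NADP reductase (LOC_Os02g01340, chromosome 2, 183601 to 185327) fell from 889.8 ± 81 to 635 ± 37 CPM (adjusted p = 0.00742). Counts on the list made up 16.1% ± 0.603 (SD, n = 3) of WT shoot libraries and 13.9% ± 0.436 of OX6 shoot libraries. Calvin cycle and photorespiration genes shifted downwards as well (camera adjusted p = 0.018, median −0.115; adjusted p = 0.787 with an estimated correlation), and 1 rose and 6 fell of 65 tested (1 and 11 adjusted over the list alone). Rubisco activase (LOC_Os11g47970, chromosome 11, 28934294 to 28936340) fell from 3721 ± 433 to 2578 ± 34.6 CPM (adjusted p = 0.00369). Glyceraldehyde-3-phosphate dehydrogenase A (LOC_Os04g38600, chromosome 4, 22937056 to 22939073) fell 1.5-fold (adjusted p = 0.00585), while the peroxisomal 2-hydroxy-acid oxidase GLO4 (LOC_Os07g42430, chromosome 7, 25404280 to 25405952) rose from 3.21 ± 1.04 to 6.8 ± 0.955 CPM (adjusted p = 0.00979). For chlorophyll and tetrapyrroles 1 rose and 5 fell of 34 tested (1 and 7 adjusted over the list alone). Magnesium-protoporphyrin IX monomethyl ester cyclase (LOC_Os01g17170, chromosome 1, 9874326 to 9876951), which closes a ring of the chlorophyll precursor, fell from 1469 ± 115 to 973 ± 74.9 CPM (adjusted p = 0.00149). Siroheme synthase rose from 18.8 ± 0.103 to 46.3 ± 3.58 CPM (adjusted p = 6.52e-07). Root-enriched genes made up 0.00187% ± 0.000626 of counts in WT shoots and 0.00176% ± 0.000511 in OX6 shoots. Their choice favours low WT shoot counts and leaves root tissue in WT shoots open. Of 5 root cap domain genes, singled out after their values were seen, 4 fell in OX6 shoots. LOC_Os01g73730 (chromosome 1, 42710696 to 42712138) fell from 0.937 ± 0.56 to 0.0101 ± 0.0174 CPM (136 WT and 1 OX6 counts, adjusted p = 0.000998) and LOC_Os11g05360 (chromosome 11, 2379139 to 2380413) from 3.22 ± 1.17 to 1.28 ± 0.344 CPM (adjusted p = 0.0188). Together the 5 had 4.95, 11.2 and 7.83 CPM in WT shoots, 3.02, 3.01 and 2.56 in OX6 shoots and 308 to 361 in WT roots.

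In the sucrose, starch and sugar transport list 11 rose and 7 fell of 147 tested (15 and 10 adjusted over the list alone). The rises included a trehalose-phosphate synthase (LOC_Os02g54820, chromosome 2, 33569263 to 33574120), from 66.1 ± 3.57 to 153 ± 5.72 CPM (adjusted p = 5.37e-07), and sugar transport protein 1 (LOC_Os07g37320, chromosome 7, 22353094 to 22355806), which takes up hexoses, from 41.2 ± 6.97 to 92.2 ± 6.53 CPM (adjusted p = 9.49e-06). Neutral/alkaline invertase 1 (LOC_Os01g22900, chromosome 1, 12870228 to 12874264), which splits sucrose, and beta-amylase 3 (LOC_Os10g41550, chromosome 10, 22324198 to 22327665), which degrades starch, rose 1.86-fold and 5.93-fold (adjusted p = 2.68e-05 and 2.9e-05). For glycolysis and the tricarboxylic acid cycle 2 rose and 7 fell of 163 tested (2 and 7 adjusted over the list alone), the falls including chloroplastic malate dehydrogenases LOC_Os08g33720, chromosome 8, 21054659 to 21057561 (1.64-fold, adjusted p = 0.000268) and LOC_Os07g43700, chromosome 7, 26153825 to 26156006 (1.59-fold, adjusted p = 0.000355). A 2-alkenal reductase gene of that list (LOC_Os04g41960, chromosome 4, 24858040 to 24859661) rose 2.05-fold (adjusted p = 6.35e-06).

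Among the hormone lists in shoots, for cytokinin 2 rose and 2 fell of 40 tested (2 and 4 adjusted over the list alone). Cytokinin dehydrogenases 3 (LOC_Os10g34230, chromosome 10, 18270169 to 18274977) and 4 (LOC_Os01g71310, chromosome 1, 41300203 to 41303044), which degrade cytokinin, fell 1.84-fold and 1.78-fold, and ORR9 and ORR10 rose 1.38-fold and 1.39-fold (adjusted p = 0.00225, 0.00364, 0.0333 and 0.0225). For abscisic acid 2 rose and 0 fell of 14 tested (2 and 0 adjusted over the list alone). Abscisic acid 8'-hydroxylase 1 (LOC_Os02g47470, chromosome 2, 28995717 to 28998581), which breaks the hormone down, rose from 6 ± 0.236 to 14.9 ± 3.88 CPM (adjusted p = 0.000225). The receptor PYL4 (LOC_Os03g18600, chromosome 3, 10418634 to 10419919) rose 1.7-fold (adjusted p = 0.000303). Auxin genes gave a count in which 10 rose and 5 fell of 178 tested (11 and 9 adjusted over the list alone), with IAA14 (LOC_Os03g58350, chromosome 3, 33246011 to 33247318) up 1.98-fold and SAUR36 (LOC_Os02g42990, chromosome 2, 25878901 to 25879880) down 2.51-fold (adjusted p = 0.000182 and 4.8e-05). For gibberellin 2 rose and 5 fell of 44 tested (4 and 5 adjusted over the list alone), the 2-beta-dioxygenase LOC_Os01g55240 rising 2.06-fold (adjusted p = 0.000976). In the jasmonate list 8 rose and 1 fell of 66 tested (8 and 2 adjusted over the list alone), including the repressors TIFY 11b (LOC_Os03g08330, chromosome 3, 4248884 to 4249985, 1.93-fold) and TIFY 10a (LOC_Os03g28940, chromosome 3, 16407670 to 16410080, 1.68-fold), at adjusted p of 0.00025 and 0.00121. In the ethylene list 12 rose and 9 fell of 116 tested (17 and 12 adjusted over the list alone). The transcription factor ETHYLENE INSENSITIVE 3-like 1 (LOC_Os07g48630, chromosome 7, 29115869 to 29118681) rose 1.68-fold and ERF9 (LOC_Os04g52090, chromosome 4, 30939177 to 30940275) fell 2.61-fold (adjusted p = 0.000437 and 1.94e-06).

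Among the genes called in shoots, most of the pathogenesis-related and cell wall genes were higher in OX6. Of pathogenesis-related genes 19 rose and 2 fell of 257 tested (25 and 4 adjusted over the list alone), such as a Bowman-Birk trypsin inhibitor (LOC_Os03g60840, chromosome 3, 34566988 to 34568087), from 112 ± 20.8 to 266 ± 21.1 CPM (adjusted p = 7.89e-06), and WRKY46 (LOC_Os09g16510, chromosome 9, 10128825 to 10131136), 2.04-fold (adjusted p = 1.61e-05). For diterpenoid phytoalexins 1 rose and 1 fell of 38 tested (1 and 1 adjusted over the list alone). A homologue of momilactone A synthase (LOC_Os07g46852, chromosome 7, 28004858 to 28006379) rose from 51.7 ± 6.62 to 142 ± 30.4 CPM (adjusted p = 9e-06). In the cell wall list 22 rose and 8 fell of 248 tested (29 and 16 adjusted over the list alone). Xyloglucan endotransglucosylase 30 (LOC_Os02g46910, chromosome 2, 28621982 to 28624683) and expansin-like A1 (LOC_Os03g04020, chromosome 3, 1831332 to 1833506) rose 2.2-fold and 1.94-fold, while expansin-A2 (LOC_Os01g60770, chromosome 1, 35145516 to 35147338), which loosens walls, fell 2.3-fold (adjusted p = 5.65e-06, 7.3e-06 and 3.75e-05). For class III peroxidases 11 rose and 9 fell of 96 tested (19 and 13 adjusted over the list alone), peroxidase 16 (LOC_Os06g48030, chromosome 6, 29050768 to 29054613) rising 2.09-fold (adjusted p = 1.87e-05) and a further peroxidase 2 gene (LOC_Os01g18930, chromosome 1, 10701626 to 10703130) falling 3.06-fold (adjusted p = 0.000557). The phenylpropanoid list leaned the other way, since 8 rose and 20 fell of 255 tested (10 and 22 adjusted over the list alone). Phenylalanine ammonia-lyase (LOC_Os12g33610, chromosome 12, 20292893 to 20295410), the entry enzyme, fell from 58.5 ± 7.76 to 30.1 ± 2.02 CPM (adjusted p = 4.27e-05), while anthocyanidin 3-O-glucosyltransferase LOC_Os06g09240 rose 1.89-fold (adjusted p = 0.000155). Of the aquaporins 3 rose and 1 fell of 39 tested (4 and 1 adjusted over the list alone), with a PIP2-6 gene (LOC_Os04g16450, chromosome 4, 8948206 to 8950028) rising 1.66-fold (adjusted p = 0.00044).

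For heat shock proteins in shoots 3 rose and 10 fell of 145 tested (3 and 11 adjusted over the list alone), the 70 kDa cognate LOC_Os03g16860 falling from 83.7 ± 5.11 to 56.5 ± 6.17 CPM (adjusted p = 0.00339). In the late embryogenesis list 4 rose and 0 fell of 67 tested (4 and 0 adjusted over the list alone). In the ribosomal list 1 rose and 4 fell of 344 tested (0 and 0 adjusted over the list alone). Of the symbiosis genes 3 rose and 3 fell of 45 tested (4 and 4 adjusted over the list alone). Of the transposon-related genes 14 rose and 9 fell of 547 tested (13 and 8 adjusted over the list alone). Histone and cell cycle genes gave a count in which 0 rose and 0 fell of 124 tested (0 and 0 adjusted over the list alone), histone H3.3 (LOC_Os03g27310, chromosome 3, 15645605 to 15648242) having 508 ± 57.2 CPM in WT and 559.8 ± 12.6 CPM in OX6. For the circadian clock 0 rose and 0 fell of 8 tested (3 and 1 adjusted over the list alone), with GIGANTEA at 1002 ± 155 CPM in WT and 856 ± 61.9 CPM in OX6. The 29 shoot lists that camera did not call had adjusted p of 0.0708 to 0.988. Median and mean differed in sign for the carotenoid cleavage, phosphate, nitrate, mineral transporter, sucrose, jasmonate, ethylene, peroxidase, clock, symbiosis and transposon lists.

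The shoot count fell to 865, 752 and 708 without OX6 shoot replicate 1, 2 or 3 and rose to 2459 (1294 higher, 1165 lower) in 1 fit of all 12 libraries, and the Calvin cycle call ended without WT shoot replicate 3 (adjusted p = 0.056) or OX6 shoot replicate 2 (adjusted p = 0.213). Without WT shoot replicate 1 or 2 or 1 of the OX6 shoot libraries, 16 named calls ended at adjusted p of up to 0.205, namely CCD8 homolog A, CCD4 (LOC_Os02g47510), phytoene synthase, D27, DWARF 53-LIKE, ORR9, ORR10, nicotianamine synthase 3, ferredoxin--NADP reductase, chlorophyll a-b binding protein 1, glyceraldehyde-3-phosphate dehydrogenase A, GLO4, the nitrate reductase gene LOC_Os08g36480, peroxidase 2 (LOC_Os07g48010), dirigent protein 4 and the root cap gene LOC_Os11g05360, of which CCD8 homolog A, CCD4 and chlorophyll a-b binding protein 1 also lost theirs in the 12-library fit (0.0507, 0.0876 and 0.0725).

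**Figure D2:**
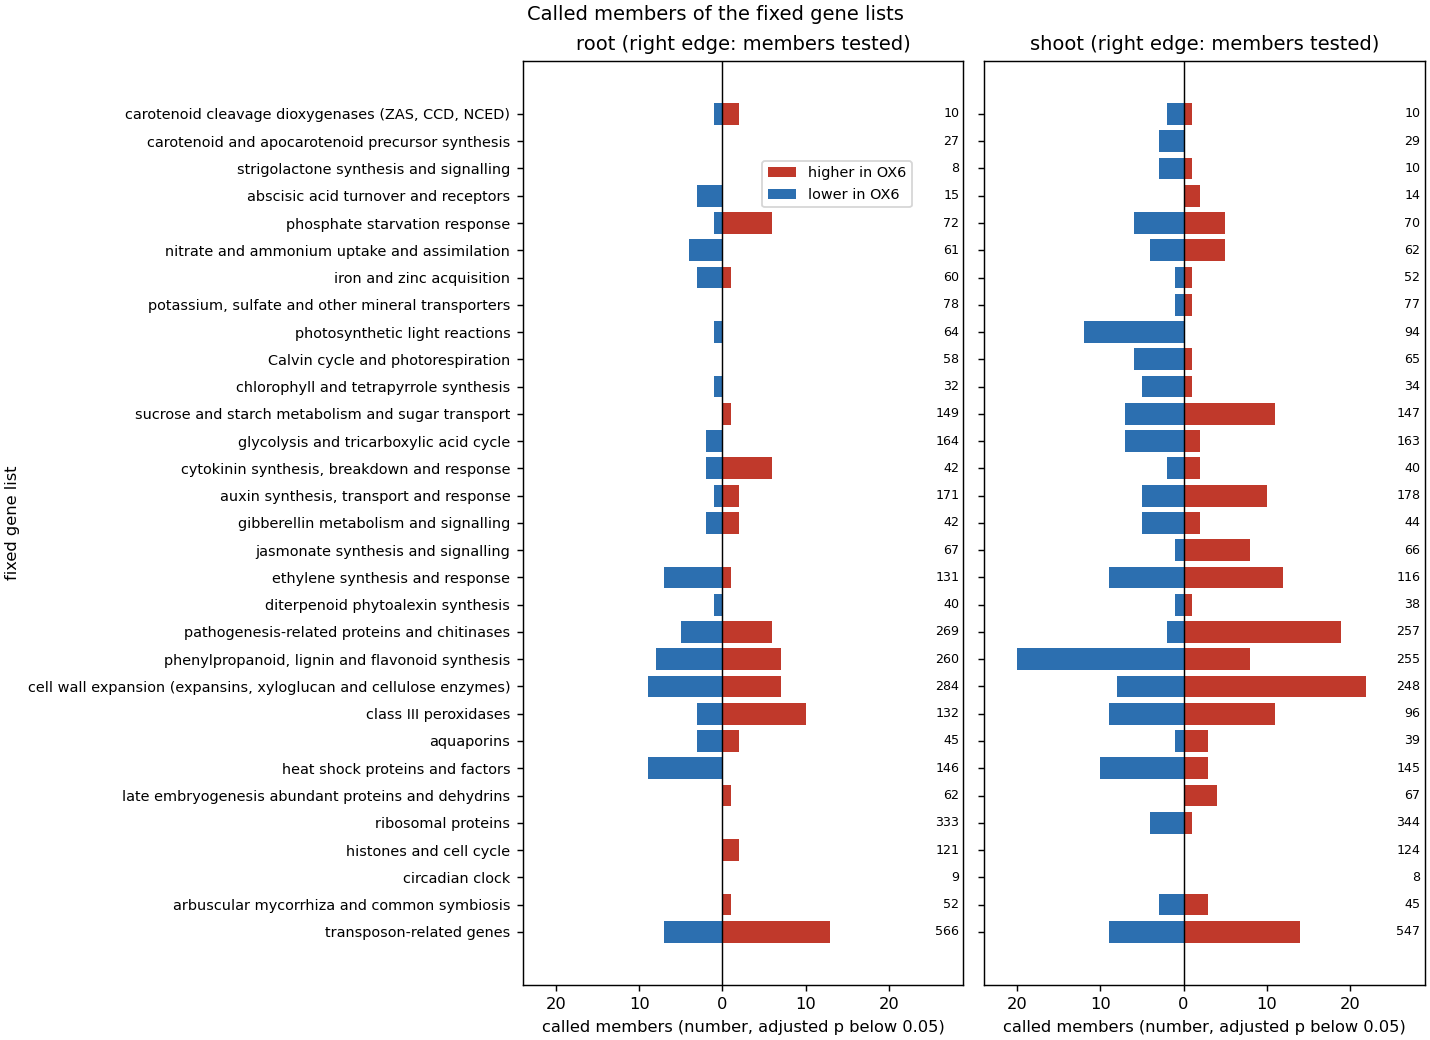
Members of each fixed gene list called in roots (left) and shoots (right) at an adjusted p under 0.05, as numbers of genes higher (red) or lower (blue) in OX6, with the members tested at the right edge. Light reaction genes have 12 lower members of 94 in shoots and 1 of 64 in roots, and pathogenesis-related genes 19 higher of 257 in shoots.

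Whether the effect of OX6 differed between tissues was tested with the genotype by tissue interaction. Apart from ZAS, the smallest adjusted p was that of nitrate reductase gene LOC_Os02g53130, which fell in roots and rose in shoots (difference of log2 fold changes 3.13, SE 0.174, adjusted p = 2.19e-08), LOC_Os08g36480 differing by 1.33 (SE 0.217, adjusted p = 0.00251). Siroheme synthase went the same 2 ways (1.67, SE 0.111, adjusted p = 2.15e-07). ERF057, which fell in roots, differed by 2.53 (SE 0.185, adjusted p = 7.6e-07). ACR6 (LOC_Os04g32110, chromosome 4, 19269218 to 19271345), with ACT domains, differed by 1.64 (SE 0.126, adjusted p = 1.29e-06), with 192.9 CPM in WT and 173.5 CPM in OX6 roots and a rise from 55 to 153.3 CPM in shoots. ZAS itself rose further in shoots (5.56, SE 0.24, adjusted p = 7.11e-10; 6.26 without WT shoot replicate 2).

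By list, 5 of 72 nitrate and ammonium genes and 9 of 158 sucrose and starch genes had a higher OX6 effect in shoots, and 0 a lower one. In the cytokinin list 1 of 45 was higher and 8 were lower in shoots, including ORR6 (−1.39, SE 0.131, adjusted p = 9.67e-06). Abscisic acid genes had 3 of 16 higher and 0 lower, ethylene genes 7 of 141 higher and 2 lower, and glycolysis genes 0 of 168 higher and 4 lower. Light reaction genes had 0 of 94 in either direction. Across 29042 genes tested, 572 were called, 371 with the higher effect in shoots and 201 with the lower, and 3859 had an unadjusted p under 0.05. The lean was less under upper-quartile scaling (312 and 278), and it turned without WT shoot replicate 1 (326 and 375) or WT shoot replicate 3 (312 and 353). Of the 572, 334 had been called in shoots alone, 78 in roots alone, 57 in both and 103 in neither. DESeq2 called 1207 genes (606 higher, 601 lower).

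**Figure D3:**
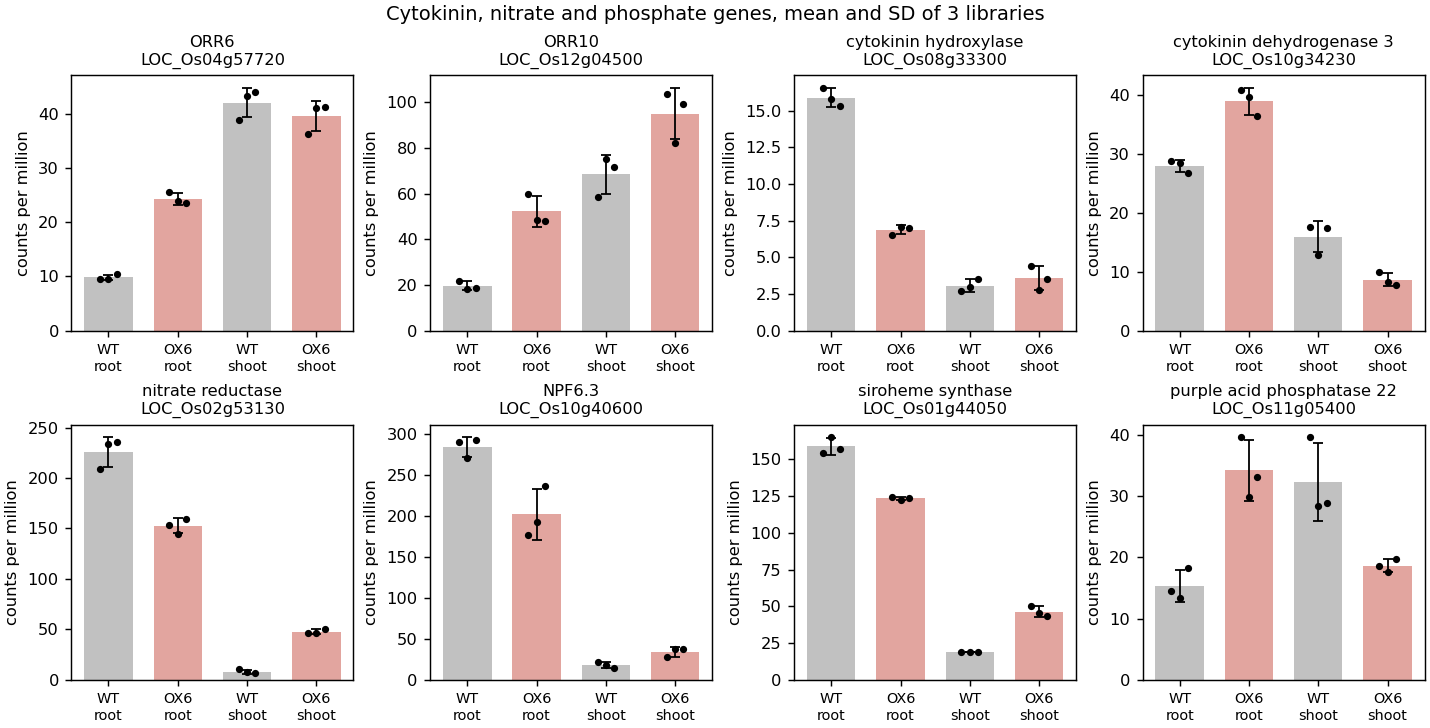
Expression in CPM, scaled within each tissue, of cytokinin, nitrate and phosphate genes in the 4 groups, with each library as a point and bars at the mean with its SD (n = 3). Nitrate reductase gene LOC_Os02g53130 goes from 226 to 153 CPM in roots and from 8.11 to 47.7 CPM in shoots, and ORR6 from 9.85 to 24.3 CPM in roots.

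Genes called in both tissues were counted among the 23939 genes tested in both. Of 171 such genes, 79 rose in both, 58 fell in both, 26 fell in roots and rose in shoots, and 8 rose in roots and fell in shoots. Independent lists would share 33.7 genes in all and 7.5, 8.85, 11.7 and 5.7 in those classes. Among genes that moved the same way, the mitochondrial import receptor TOM40-1 (LOC_Os03g20750, chromosome 3, 11742589 to 11747956) fell 2.02-fold in roots and 2.55-fold in shoots (adjusted p = 2.17e-07 and 1.62e-06). A gene with a no apical meristem-associated domain (LOC_Os11g17954, chromosome 11, 10081786 to 10086180) rose from 0.0271 ± 0.047 to 3.63 ± 0.249 CPM in roots and from 0.0344 ± 0.03 to 2.6 ± 0.507 CPM in shoots (adjusted p = 2.8e-07 and 2.34e-06), with 3 and 5 counts over the WT libraries (root log2 fold change 6.89, or 10.06 without WT root replicate 3). The copia-type gag gene LOC_Os02g34760 also fell in shoots, from 3.17 ± 0.259 to 0.182 ± 0.127 CPM (adjusted p = 9e-06; log2 fold change −4.11, or −4.82 without OX6 shoot replicate 3), and the Copia protein gene rose in both as given above.

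Of the 34 genes called in opposite directions, 5 are named here by the smallest larger adjusted p, nitrate reductase gene LOC_Os02g53130 and 4 others. Dehydration-responsive element-binding protein 1A (LOC_Os09g35030, chromosome 9, 20403149 to 20404332), a transcription factor of cold responses, fell from 6.9 ± 1.58 to 2.72 ± 0.433 CPM in roots and rose from 11.6 ± 2.72 to 74.6 ± 14.7 CPM in shoots (adjusted p = 0.000484 and 1.36e-06). An F-box/kelch-repeat gene (LOC_Os02g11790, chromosome 2, 6092981 to 6095907) fell 2.01-fold in roots and rose 2.63-fold in shoots (adjusted p = 0.000383 and 0.00017). The carrier gene SLC25A44 (LOC_Os03g07890, chromosome 3, 4014426 to 4016478) fell 1.57-fold and rose 1.82-fold (adjusted p = 0.000607 and 0.000166), and a LON protease domain gene (LOC_Os03g29540, chromosome 3, 16836622 to 16840754) fell 1.99-fold and rose 1.62-fold (adjusted p = 2.92e-05 and 0.000645). Without OX6 shoot replicate 3 the count of shared genes was 107.

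**Figure D4:**
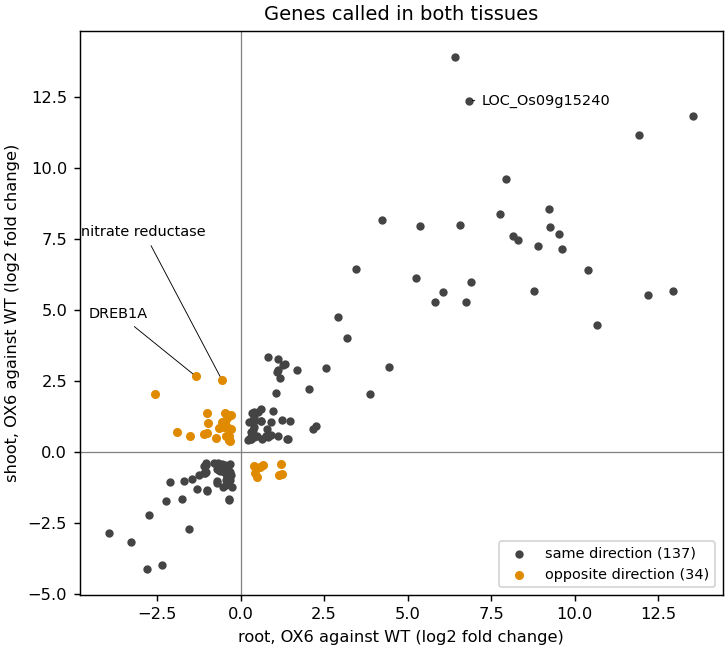
Log2 fold changes of OX6 against WT in roots (horizontal axis) and shoots (vertical axis) for the 171 genes called in both tissues. Grey points (137) moved the same way and orange points (34) opposite ways, ZAS lying at 6.82 and 12.38.

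The WT root and shoot libraries were compared to check the tissue labels. Of 29042 genes tested, 21193 differed, 10924 higher in roots and 10269 higher in shoots, and 13762 of them by at least 2-fold. Light reaction genes took 16.1% ± 0.603 of counts in WT shoots and 0.0343% ± 0.00279 in WT roots. The 200 most root-enriched genes took 3.58% ± 0.0252 of counts in WT roots, and the 200 most shoot-enriched genes 18.8% ± 0.153 of counts in WT shoots.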

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

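The tests of shoot RNA in roots by genes outside the photosynthesis lists, of a deviating OX6 root library, of root tissue in OX6 shoots, of the genes far higher in OX6 in both tissues, and of scaling and time of day for the nitrate genes were chosen only after the result was seen.

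The effect of OX6 differed between roots and shoots by the interaction test for 572 of 29042 genes (1.97%). It differed for 60 of 117 named genes tested (39 higher and 21 lower in shoots), while 57 had no call. Many named genes were chosen for a call in a tissue, a small interaction p or opposite directions. Their high share follows from that choice and is no separate result. Values below are shoot minus root log2 fold changes. Of 100 splits within the tissues, 2 gave as many genes, the real split with 572 and another with 1559, a share under 0.05, which argues against a random grouping of both tissues as the source. The split with 1559 kept both real groupings and turned the sign in shoots, so it points to a structure of the samples, effects of the same direction in both tissues. Splits real in neither tissue gave 0 to 2 genes, those real in roots alone 16 to 29 and those real in shoots alone 290 to 546, so most of the count also arose with a random root grouping.

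ZAS (LOC_Os09g15240) differed by 5.56. Of 72 nitrate and ammonium genes 5 were higher in shoots and 0 lower, and named nitrogen genes gave 3.13 and 1.33 for nitrate reductase genes LOC_Os02g53130 and LOC_Os08g36480, 1.67 for siroheme synthase (LOC_Os01g44050), 1.79 for ammonium transporter 2 member 3 (LOC_Os01g61510) and 1.39 for NPF6.3 (LOC_Os10g40600). Transcription factors and regulators gave 2.53 for ERF057 (LOC_Os03g09170), 4.03 for DREB1A (LOC_Os09g35030), 1.21 for WRKY46 (LOC_Os09g16510), 0.67 for ETHYLENE INSENSITIVE 3-like 1 (LOC_Os07g48630), 1.64 for ACR6 (LOC_Os04g32110) and −1.29 for ACR3 (LOC_Os02g34990). Cytokinin genes were −1.39 for ORR6 (LOC_Os04g57720), −0.93 for ORR9 (LOC_Os11g04720), −0.93 for ORR10 (LOC_Os12g04500), −1.35 and −1.04 for cytokinin dehydrogenases 3 and 4 (LOC_Os10g34230 and LOC_Os01g71310) and 1.43 for cytokinin hydroxylase (LOC_Os08g33300). Carotenoid and strigolactone genes were −1.99 for CCD8 homolog A (LOC_Os01g38580), 1.73 for the NCED gene LOC_Os12g42280, −1.0 for beta-carotene hydroxylase 2 (LOC_Os04g48880), −2.58 for D27 (LOC_Os08g02210; 4 counts over the WT and 20 over the OX6 root libraries) and −0.80 for DWARF 53 (LOC_Os11g01330).

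Other hormone genes gave 1.51 for the gibberellin 2-beta-dioxygenase LOC_Os01g55240, 1.0 for PYL4 (LOC_Os03g18600), 1.39 for abscisic acid 8'-hydroxylase 1 (LOC_Os02g47470), −1.38 for SAUR36 (LOC_Os02g42990), and 1.01 and 1.27 for TIFY 10a and TIFY 11b (LOC_Os03g28940 and LOC_Os03g08330). Mineral transport and phosphate genes gave −1.94 for purple acid phosphatase 22 (LOC_Os11g05400), 0.91 for phosphate transporter 1-1 (LOC_Os03g05620), 0.87 for potassium transporter 7 (LOC_Os07g47350), 1.22 for vacuolar iron transporter 1.2 (LOC_Os09g23300) and −1.17 for nicotianamine synthase 3 (LOC_Os07g48980). Sugar and organic acid genes gave 2.63 for beta-amylase 3 (LOC_Os10g41550), 1.05 for sugar transport protein 1 (LOC_Os07g37320), 0.90 for a trehalose-phosphate synthase (LOC_Os02g54820), 0.80 for neutral/alkaline invertase 1 (LOC_Os01g22900), and −1.0 and −0.68 for malate dehydrogenases LOC_Os07g43700 and LOC_Os08g33720. Cell wall and defence genes gave 0.85 for expansin-like A1 (LOC_Os03g04020), −0.94 for expansin-A2 (LOC_Os01g60770), 0.95 for xyloglucan endotransglucosylase 30 (LOC_Os02g46910), 0.82 for peroxidase 16 (LOC_Os06g48030), −0.68 for peroxidase SPC4 (LOC_Os01g73170), −3.39 for glucosidase 13 (LOC_Os07g35350; 28 and 6 counts in WT and OX6 shoots), 1.23 for the Bowman-Birk inhibitor (LOC_Os03g60840), 1.91 for momilactone A synthase homologue LOC_Os07g46852, and 1.88 for nematode resistance protein-like HSPRO2 (LOC_Os01g63690). Further defence genes gave −1.34 for the anthocyanidin glucosyltransferase (LOC_Os06g09240), 2.34 for the wound-induced protein LOC_Os04g54240 and 1.72 for receptor-like kinase 15 (LOC_Os11g10710). The remaining named genes gave 1.70 for LOC_Os03g29540, 1.52 for SLC25A44 (LOC_Os03g07890), 2.4 for LOC_Os02g11790, 1.80 for LOC_Os10g14180, 1.83 for RICESLEEPER 2 (LOC_Os06g40240), 1.07 for RDUF1 (LOC_Os07g43740), and −6.49 and −1.58 for the root cap genes LOC_Os01g73730 (136 and 1 counts over the WT and OX6 shoot libraries) and LOC_Os11g05360. D27 in roots and glucosidase 13 in shoots were too low to be tested within the tissue, so these values rest on counts near 0 there.

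Other splits were counted for each comparison. In roots 1 of the 10 splits, the real one, gave 753 genes and the highest other 2. In shoots 1 of the 10 splits gave 1481 and the highest other 1, and in the WT tissue comparison 1 of the 10 gave 21193 and the highest other 0. For gene lists, 3 of 10 root splits gave as many as the real 4 (highest other 6) and 9 of 10 shoot splits as many as the real 2 (highest other 7). The number of called lists therefore did not set the genotypes apart from random groupings in either tissue. A camera call is thus weak evidence of a genotype effect on a list. For the gene counts, no share under 0.05 can be had with 10 splits. For genes called in both tissues 1 of 100 pairs of splits gave 171, the highest other being 1, which decides nothing on the overlap because each other split called 0 to 2 genes in its tissue.

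The light reaction list shifted downwards in both tissues by camera (adjusted p = 0.744 in roots and 0.787 in shoots with an estimated correlation), with 1 of 64 members called in roots and 12 of 94 in shoots, and in roots the 35 members with at most 10% of their level from carried-over shoot RNA had a median log2 fold change of −0.0266 (quartiles −0.204 and 0.0865) and the other 29 a median of −0.743. Carried-over shoot RNA was 0.0333% of counts (SD 0.00854, n = 3) in WT and 0.0213% (SD 0.00835) in OX6 by the 200 shoot-enriched genes, but 0.0205% (SD 0.00262) and 0.0225% (SD 0.00495) by the 165 outside the photosynthesis lists. The 6 of those tested in roots had a median of −0.596 (quartiles −0.795 and −0.47), which goes with less shoot tissue. So does the median of −0.0266, since a value within 0.1 of 0 was set beforehand as the sign of this cause. The summed share does not. Its genes were ranked by fold in these WT libraries, which favours low WT root counts and lowers the WT share. It therefore cannot count against less shoot tissue. Less shoot tissue in the OX6 roots and an effect of the genotype cannot be told apart for the root part. The root median of −0.306 was −0.19 without WT root replicate 1 and −0.162 without OX6 root replicate 1 (camera adjusted p = 0.0209). The remaining fall argues against the latter library alone as the source. The camera p adds little, given the lists called in other groupings. For the shoot part, the root-high share moved by −0.00302% of its root level, against root tissue in OX6 shoots, and the list median was −0.184 under RLE and −0.21 under upper-quartile scaling where that of all genes was −0.00498 and −0.0312, against scaling, while other technical sources were not tested and an effect of the genotype stays open as a hypothesis.

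A set of 30 genes was called in both tissues at 8-fold or more in the same direction or without a count in 1 genotype, 29 higher and 1 lower in OX6 (LOC_Os08g05690, ABC transporter B family 19). The 28 higher genes besides ZAS had a median summed count of 485.5 over the 6 OX6 libraries, which decides nothing on few counts because each gene had passed the count filter in both tissues. They lay on 11 chromosomes with at most 10.7% in any window of 1 Mb, which argues against the neighbourhood of a single insertion site. The exception is 1 run of 3 near neighbours on chromosome 7, LOC_Os07g32680, LOC_Os07g32700 and LOC_Os07g32710, and as many such runs arose in 6 of 10000 random placements of 30 genes. With 1 overexpressing line, an effect of ZAS and another difference between the stocks cannot be told apart for these genes. The same limit holds for every other OX6 against WT call.

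Nitrate reductase gene LOC_Os02g53130, NPF6.3 and siroheme synthase were lower in OX6 roots and higher in OX6 shoots. The root log2 fold change nearest to 0 over RLE, upper-quartile and 12-library scaling was −0.356, which argues against scaling. In the 12-library fit the root call of NPF6.3 ended (adjusted p = 0.143, log2 fold change −0.50), as it did without WT root replicate 3 (0.067) or OX6 root replicate 2 (0.0667). Of 8 clock genes in shoots, 3 had a 95% interval of the log2 fold change above 0 (PRR1 and 2 PRR95 genes) and 1 below (LHY), the largest change being 0.316 in size, and of 9 in roots 0 lay above and 1 below. These shifts are small but leave sampling at another time of day open, so it and an effect of the genotype cannot be told apart here.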

How the results depend on the processing

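Leaving out models without a locus identifier or plastid-type names and thinning WT shoot replicate 2 were chosen after seeing the data. Root calls (753) were 224 at an absolute log2 fold change of at least 1, 344 at adjusted p under 0.01, 293 with all 12 libraries in 1 fit, and 407 to 773 without 1 library (459 without WT root replicate 2, 407 without WT root replicate 3). Shoot calls (1481) were 397, 707, 2459 and 708 to 1877 (865, 752 and 708 without OX6 shoot replicate 1, 2 or 3). The lowest counts shared 390 of 407 and 687 of 708 genes with the reported calls. Stricter limits lower the counts by construction. Fewer samples alone do not explain the counts without 1 library, which went both ways. Root calls rose to 773 without OX6 root replicate 1. Shoot calls were 708 to 865 without 1 OX6 library and 1201 to 1877 without 1 WT library. The cause of these differences, of 293 and of 2459 was not tested. DESeq2 gave 1207 interaction genes (606 higher, 601 lower), cause not tested, and 382 to 701 without 1 library. Genes in both tissues were 59 at an absolute log2 fold change of at least 1, and 107 to 196 without 1 library (107 without OX6 shoot replicate 3). Tissue calls were 20174 to 21220 without 1 library, leaning to shoots without WT shoot replicate 1 (10493 and 10608). Lists called were 0 and 0 with an estimated correlation, 1 (root, higher, the carotenoid cleavage list, which holds ZAS and had a median of −0.332) and 0 by fry, 3 to 5 in roots and 2 to 4 in shoots without 1 library (4 without WT shoot replicate 2). ZAS was at 6.77 to 6.86 in roots and 12.16 to 13.10 in shoots without 1 library (13.10 without WT shoot replicate 2).

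Same-numbered libraries of the genotypes correlated at −0.0808, 0.0753 and 0.00645 in roots and −0.0215, −0.0103 and 0.0459 in shoots. Root and shoot libraries of the same number correlated at −0.0234 to 0.0223. Not every library correlated best with its own number. These values gave no sign of pairing, but with 3 libraries per group they cannot exclude shared plants or batches. The interaction and tissue fits treated all 12 libraries as independent. With the replicate block the counts were 796, 1454, 497, 20878 and 179, lists 3 and 2, and ZAS 6.825 and 12.41. The block ended the heat shock call (adjusted p = 0.0546) and that of LOC_Os02g47510 in shoots (0.0537).

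Directions turned for uncalled genes near 0. D14 (LOC_Os03g10620) in roots was 0.0013 under upper-quartile scaling, 0.0051 with voom, 0.0051 with the block, 0.14 without WT root replicate 2 and 0.033 without OX6 root replicate 3. NIP2-1 (LOC_Os02g51110) was 0.027 and 0.033 without the same libraries, CCD7 (LOC_Os04g46470) −0.0083 without WT root replicate 2, LOC_Os01g54270 0.095 without OX6 root replicate 3 and GIGANTEA (LOC_Os01g08700) 0.00060 without OX6 root replicate 1. Without 1 library these 5 ranged from −0.082 to 0.14, −0.13 to 0.033, −0.0083 to 0.35, −0.47 to 0.095 and −0.0525 to 0.00060. In shoots LOC_Os12g44310 was 0.014 without WT shoot replicate 2, 0.0098 without WT shoot replicate 3, 0.014 and 0.003 without OX6 shoot replicate 2 or 3 and 0.0016 with WT shoot replicate 2 thinned, and LOC_Os12g42280 was −0.16 without OX6 shoot replicate 2, their ranges without 1 library being −0.031 to 0.014 and −0.16 to 0.46. The cause was not tested. Without 1 library 4 named root calls and 16 named shoot calls ended. The root ones were PYL2 without WT root replicate 2 (0.114) or OX6 root replicate 2 (0.0687), NPF4.4 without OX6 root replicate 1 (0.0748), NPF6.3 without WT root replicate 3 (0.067) or OX6 root replicate 2 (0.0667) and LOC_Os01g55240 without WT root replicate 2 (0.0662), WT root replicate 3 (0.0768), OX6 root replicate 2 (0.131) or OX6 root replicate 3 (0.0974).

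Leaving out WT shoot replicate 1 ended CCD8 homolog A (adjusted p = 0.081), LOC_Os02g47510 (0.0637) and ORR9 (0.0782). Leaving out WT shoot replicate 2 ended peroxidase 2 (LOC_Os07g48010, 0.0975), CCD8 homolog A (0.105), phytoene synthase (0.0714) and root cap gene LOC_Os11g05360 (0.142). Leaving out OX6 shoot replicate 1 ended peroxidase 2 (0.132), dirigent protein 4 (0.0987), CCD8 homolog A (0.136), LOC_Os02g47510 (0.144), D27 (0.125), DWARF 53-LIKE (0.0866), ferredoxin--NADP reductase (0.0505), chlorophyll a-b binding protein 1 (0.0785), glyceraldehyde-3-phosphate dehydrogenase A (0.0505), GLO4 (0.0537), LOC_Os08g36480 (0.059), ORR10 (0.146) and ORR9 (0.205). Leaving out OX6 shoot replicate 2 ended dirigent protein 4 (0.0988), CCD8 homolog A (0.0548), LOC_Os02g47510 (0.103), phytoene synthase (0.0781), D27 (0.0847), nicotianamine synthase 3 (0.050), ferredoxin--NADP reductase (0.0662) and LOC_Os11g05360 (0.104). Leaving out OX6 shoot replicate 3 ended peroxidase 2 (0.0739), dirigent protein 4 (0.0748), CCD8 homolog A (0.111), LOC_Os02g47510 (0.108), phytoene synthase (0.122), D27 (0.115), DWARF 53-LIKE (0.0681), chlorophyll a-b binding protein 1 (0.0687), glyceraldehyde-3-phosphate dehydrogenase A (0.0606), GLO4 (LOC_Os07g42430, 0.0787), LOC_Os08g36480 (0.0606), ORR10 (0.13), ORR9 (0.147) and LOC_Os11g05360 (0.116).

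The block ended no other named call, and RLE and upper-quartile scaling, both count filters, DESeq2 and limma-voom ended none of those tested, the CPM filter leaving root cap gene LOC_Os01g73730 untested. CCD4 gene LOC_Os12g24800 in shoots became called under upper-quartile scaling (0.0444), no filter (0.00197), the CPM filter (0.0478), DESeq2 (0.0233) and without WT shoot replicate 1 (0.00303), LOC_Os03g44380 without WT shoot replicate 3 (0.0286) LOC_Os03g52860 in roots without OX6 root replicate 3 (0.00824) and nitrate reductase gene LOC_Os08g36480 in roots with DESeq2 (2.98e-07), voom (0.0056), the block (4.21e-05), all 12 libraries in 1 fit (0.0345) and without OX6 root replicate 1 (0.022) or 2 (0.00684). Depth limits genes near 0, as for ZAS with 5, 26 and 7 counts in WT shoots (SE 0.214, against 0.0845 in roots). The planned fits without plastid- and mitochondrion-encoded genes were not run because those lists matched 0 models.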

Other observations

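Protein domains were tested for enrichment among called genes after the data were seen, against 19374 tested genes with a domain in roots and 19152 in shoots, by Fisher's exact test adjusted over 1163 and 1168 domains. The test treats neighbouring genes as independent. Wound-induced protein genes fell in roots, 9 of 11 tested (adjusted p = 5.85e-12), 6 of them in LOC_Os04g54210 to LOC_Os04g54310. AP2 domain transcription factors had 10 of 112 lower in roots (adjusted p = 0.0111) and 15 of 105 higher in shoots (0.000564). Among genes higher in roots were 5 of 24 with a response regulator receiver domain (ORR2, ORR4, ORR6, ORR9 and ORR10, adjusted p = 0.00426) and 10 of 136 peroxidases (0.00426). The rest were DUF3355 with 3 of 7 higher (0.0205), and FCS-type zinc fingers with 5 of 27 and pectinesterases with 5 of 28 lower (0.0268 each).

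In shoots, acid phosphatases of the HAD superfamily were higher, 7 of 14 (adjusted p = 7.92e-05), as were glycosyltransferase family 20 genes, the trehalose-phosphate synthases, with 6 of 10 (0.000106). Jasmonate repressors with a tify domain had 7 of 19 higher (0.000502) and xyloglucan endotransglycosylases 7 of 22 (0.00104). Pollen Ole e I-like proteins had 6 of 27 higher (0.0304), molybdopterin-binding oxidoreductases 3 of 5 (0.0387) and GDSL lipases 10 of 82 (0.0421). Lower in shoots were 18 of 145 UDP-glycosyltransferases (8.85e-05), 7 of 20 chlorophyll a-b binding proteins (0.000335), 4 of 5 genes with a root cap domain (0.001) and 4 of 11 malate dehydrogenases (0.0348).

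Of the 28 genes besides ZAS higher in OX6 by the rule above, 15 had no name or domain and 3 carried the DUF3778 domain (LOC_Os07g26100, LOC_Os03g18779 and LOC_Os03g02470). The 6 without a count in the 6 WT libraries had a median summed count of 273.5 over the OX6 libraries.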
